A study of Mus musculus with 7 samples.

How the data were processed

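Libraries had been made with the Illumina TruSeq RNA kit from RNA purified on RNeasy columns with DNase treatment, per the labels' protocols. The deposited table holds FPKM, fragments scaled for transcript length and for the mapped fragments of the library, for 1 column per library. TopHat2 2.0.4 and the genome build mm10 are named, per the submitters' processing notes, with no role stated. The program that computed the FPKM and its gene annotation are not given in the sources used here. Columns were matched to samples by the sample descriptions, and 0 columns were left over. Samples were grouped by their titles into diestrus (4 libraries) and estrus (3 libraries). FPKM divides by the reads mapped in a library, so a few very abundant transcripts can lower the values of all others. The 10 highest rows took 34.2%, 18.7%, 13.8% and 12.2% of the FPKM sum in diestrus replicates 1 to 4 and 33.7%, 38.2% and 35.3% in estrus replicates 1 to 3. A share of the FPKM sum is not a share of reads, because FPKM also divides by length. The median log2 fold change of all tested genes was 0.048, so no general lowering at estrus was seen. Reads of genes with near-identical copies can be lost or split, and Gapdh, which has many processed pseudogenes, was listed at only 3.19 to 6.34 FPKM.

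FPKM are not counts, so no count model was used. Genes with at least 1 FPKM in at least 3 of the libraries used were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a 2-group design, empirical Bayes moderation with an intensity trend and two-sided p-values adjusted by the Benjamini-Hochberg method (threshold 0.05). Fold changes are estrus minus diestrus on the log2(FPKM + 1) scale, which understates the change of genes near 0. Of 13920 tested genes, 12888 had symbols in the reference tables. Coordinates are those of GRCm38, the assembly called mm10. Because FPKM from whole reads are multiples of the value of 1 read, relative depth was read from the most frequent log2 ratio (bins of 0.02) of values under 0.3 FPKM against estrus replicate 1.

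The 36 gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest increases and 10 largest decreases with an adjusted p under 0.05, a mean of at least 5 FPKM and groups that do not overlap, leaving out predicted genes, then Esr1, Pgr and Epas1, and up to 4 members with the smallest p-value from each list. The rule does not exclude rows named by GenBank accessions that begin with AK, and these were kept. Prss28, Prss29, Spink3 and S100g, and the gene families of the closing section, were chosen after their values were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Where a list member was entered under both an older and a current symbol and the table held both, the other symbol than the first one written was used. This concerned Clca1 and Clca3 in the secretory list, was settled after values had been seen, and moved the number of genes that rose from 16 to 17 and the list median from 2.45 to 3.20 (camera adjusted p from 2.64e-06 to 5.0e-07).

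The alternatives were pseudocounts of 0.1 and 5, no expression filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, no trend, robust moderation, library weights, a replicate block, and leaving out each library with the filter applied to those left. An alternative without rows named by GenBank accessions, microRNAs or small nucleolar RNAs was added after the data were seen. All 35 splits of the libraries into groups of 4 and 3 were refitted, and the smallest p that an exact permutation over them can give is 0.0286. Each named gene was also tested by such a permutation. The genes of each list that passed without each library and in each split were counted after the data were seen. The fits were tested on simulated data built from the means and spreads of the 13920 tested genes in the estrus and diestrus comparison: of 200 changed genes, 52% of those changed 2-fold and 92% of those changed 4-fold were recovered, with 9 false calls among 153, and 0 of 35 unchanged lists were called. The simulation drew genes independently, so it does not test how camera treats correlated genes. It changed only 200 genes, taken from those with higher means, while 4336 were called in the real comparison. Its recovery rates therefore do not describe that comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Chromatin, binding and protein data named in the series design were not analysed here.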

Results

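RNA sequencing measured gene expression in whole uteri of untreated CD-1 mice, an outbred laboratory stock, aged 2 months. The estrous cycle is the recurring ovarian cycle of rodents: estrus follows the peak of estradiol, and diestrus is the phase in which progesterone from the corpora lutea prevails. The diestrus group held 4 libraries and the estrus group held 3. The deposited values were FPKM for 31274 rows, of which 21444 were above 0 in at least 1 library and 13920 were tested. FPKM carries no read count, so absolute depth was unknown. The spacing of the lowest values gave a relative depth per library, from 0.92 times estrus replicate 1 in estrus replicate 3 to 1.36 times in diestrus replicate 2. Libraries of a group correlated at Spearman values of 0.916 to 0.974 and libraries of different groups at 0.820 to 0.919. On the first principal component, which held 60.2% of the variance, the estrus libraries lay at 47.0 to 59.9 and the diestrus libraries at -11.3, -36.3, -48.0 and -61.9 for replicates 1 to 4, so diestrus replicate 1 lay nearest to estrus.

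The comparison asked which genes differ between uteri at estrus and at diestrus, as part of a study of estrous cycle dependent transcription. Aoc1, Sprr2b, Sprr2a1 and Lcn2 were among the genes most increased at estrus, and Krt23, Slc5a11, Penk and Mmp3 among those most decreased. In limma on log2(FPKM + 1), 4336 genes changed at a Benjamini-Hochberg adjusted p under 0.05, 2393 higher and 1943 lower in estrus, and 1662 of them changed at least 2-fold (945 higher, 717 lower). The excess of higher genes depended on the scaling: quantile normalization gave 1684 higher and 1914 lower, and median-ratio scaling 2141 and 2125. The groups did not overlap at 5646 tested genes, or 40.6%, against 5.71% by chance. The count rested on single libraries: it was 2559 without diestrus replicate 4, 2633 without estrus replicate 1 and 1433 without estrus replicate 2. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries, which can be technical.

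Among the genes most increased at estrus, Aoc1, the diamine oxidase that degrades histamine and putrescine (GRCm38 chromosome 6, 48872896 to 48909188, protein-coding), rose from 5.08 ± 3.86 FPKM (SD, n = 4) to 240.1 ± 183 (SD, n = 3), a log2 fold change of 5.14 (SE 0.66, limma adjusted p = 0.00257). Padi1, a peptidylarginine deiminase (chromosome 4, 140812983 to 140845778), rose from 51.1 ± 28.0 to 1111 ± 344 FPKM, a log2 fold change of 4.54 (SE 0.45, adjusted p = 0.00141). Lcn2, the iron-siderophore carrier lipocalin 2 (chromosome 2, 32384633 to 32388252), rose from 119.2 ± 90.5 to 2546 ± 960 FPKM (log2 4.75, SE 0.67). Unc5cl rose by 4.48, and the proteinase inhibitor Spink12 by 4.61, with an adjusted p of 0.0106 that became 0.0518 without estrus replicate 2. Sprr2b and Sprr2a1, small proline-rich proteins of cornified envelopes, had log2 fold changes of 5.04 and 4.87, and because the Sprr2 family is nearly identical in sequence, the split of reads between its members is uncertain. Rows named by GenBank accessions also met the rule for the largest increases. AK191723 was listed at 0 in all 4 diestrus libraries and at 30.6, 27.4 and 51.3 FPKM in estrus. AK178082 and AK188772 were listed at 0 in diestrus replicates 2 to 4 but at 130885 and 81.7 FPKM in diestrus replicate 1, with adjusted p values of 0.0445 and 0.0332 that rose to 0.125 and 0.106 without estrus replicate 2, and were above 0.05 too when any other library but diestrus replicate 1 was left out. In the estrus libraries AK178082 was at 137308 to 197099 FPKM and AK188772 at 105.6 to 137.4.

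Among the genes most decreased at estrus, Krt23, an acidic keratin (chromosome 11, 99477974 to 99493137), fell from 62.4 ± 47.8 to 0.82 ± 0.58 FPKM, a log2 fold change of -4.70 (SE 0.74, adjusted p = 0.00479). Slc5a11, a sodium-coupled inositol transporter (chromosome 7, 123214780 to 123273253), fell from 43.7 ± 27.8 to 1.03 ± 1.14 FPKM (log2 -4.23, SE 0.73). Mmp3, the matrix metalloproteinase stromelysin 1 (chromosome 9, 7445822 to 7455975), fell from 23.5 ± 20.3 to 0.59 ± 0.20 FPKM (log2 -3.63, SE 0.53). Pamr1, the metallothionein Mt3 and the noradrenaline transporter Slc6a2 had log2 fold changes of -3.33, -3.21 and -3.05, with adjusted p values of 0.00334, 0.00262 and 0.00821. Penk, the enkephalin precursor, had a log2 fold change of -3.72 and an adjusted p of 0.0152, which became 0.0703 without estrus replicate 2. Irg1 and Cwh43 had log2 fold changes of -3.41 and -3.35, and their adjusted p values of 0.0206 and 0.0241 became 0.084 and 0.0914 without estrus replicate 2. The adjusted p was also above 0.05 for Irg1 without estrus replicate 1 (0.0542), and for Cwh43 without diestrus replicate 4 (0.0588) or estrus replicates 1 (0.0633) or 3 (0.0547). AK192194, a row named by a GenBank accession, had a log2 fold change of -3.86 and an adjusted p of 0.0241, which reached 0.0787 without estrus replicate 2 and was above 0.05 without any library other than diestrus replicate 1.

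**Figure D1:**
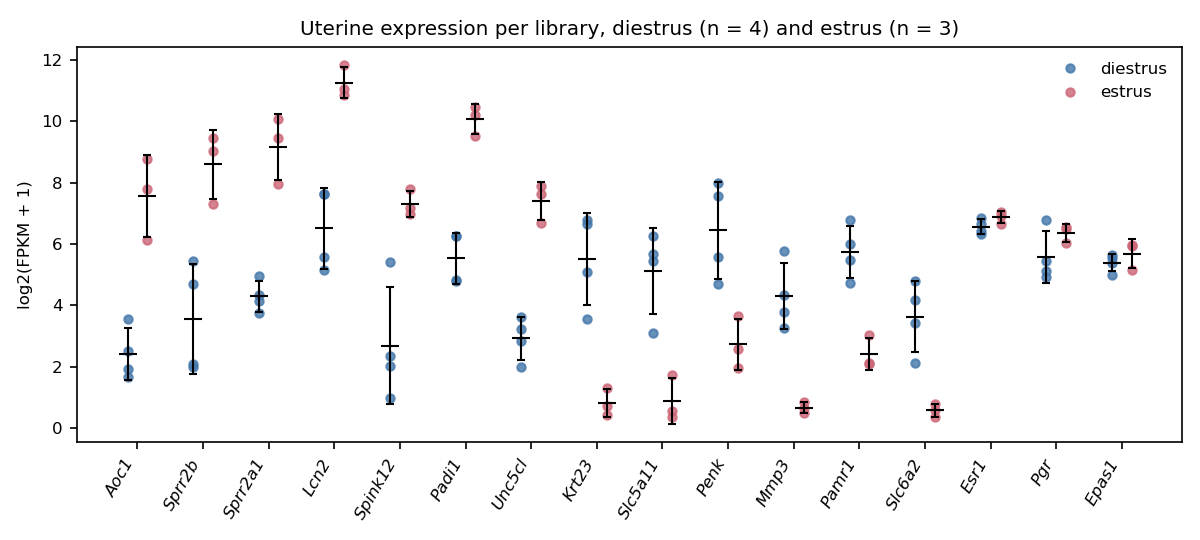
Expression per library as log2(FPKM + 1) for genes with the largest changes and for Esr1, Pgr and Epas1. Points are the 4 diestrus and 3 estrus libraries, bars are the mean and SD, and the groups overlap only at Esr1, Pgr and Epas1, whose limma adjusted p values were 0.188, 0.187 and 0.378.

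Esr1, Pgr and Epas1, named in the study design, did not pass the test. Esr1, the estrogen receptor alpha gene (chromosome 10, 4611593 to 5005614), stood at 94.3 ± 16.0 FPKM in diestrus and 116.7 ± 15.9 in estrus (log2 0.31, SE 0.17, limma adjusted p = 0.188). Pgr, the progesterone receptor gene (chromosome 9, 8899833 to 8968611), stood at 53.8 ± 37.4 and 81.9 ± 15.6 FPKM (log2 0.79, SE 0.43, adjusted p = 0.187). Without diestrus replicate 1, where Pgr was at 109.3 FPKM, its log2 fold change was 1.19 with an adjusted p of 0.00606. Epas1, which encodes Hif2a (chromosome 17, 86753700 to 86833410), stood at 41.6 ± 7.89 and 52.0 ± 15.2 FPKM (log2 0.29, SE 0.24, adjusted p = 0.378). In the list of nuclear receptors and their partners, 2 of 24 tested genes rose and 4 fell, or 2 and 2 adjusted over the list alone. Leaving out single libraries gave 1 to 3 rises and 2 to 4 falls, with 1 and 2 without estrus replicate 2. Greb1, an estrogen receptor cofactor, rose by 1.31, and Nr2f2 and Foxa2, transcription factors of stroma and glands, fell by 0.78 and fell by 1.06.

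Of 21 tested epithelial secretory genes known to be induced by estrogen, 17 rose and none fell, the same counts as adjusted over the list alone, with a median log2 fold change of 3.20. Padi4 rose by 3.38 and Padi2 by 4.17. Of 22 tested early estrogen response genes, 9 rose and 2 fell, also when adjusted over the list alone, among them the transcription factor Klf4, which rose by 2.51, and the activin subunit Inhbb, which rose by 2.49. Of 24 tested progesterone response genes, none rose and 10 fell, or 13 adjusted over the list alone, with a median of -1.31. Hoxa10 fell from 157.4 ± 40.6 to 36.0 ± 2.58 FPKM, Hoxa11 from 114.4 ± 34.2 to 27.3 ± 2.06, and the hedgehog pathway genes Gli1 and Ptch1 fell by 2.81 and fell by 1.31. Among 25 tested Wnt pathway genes, 1 rose and 14 fell, or 1 and 15 adjusted over the list alone. Dkk3, Lef1 and the secreted inhibitor Sfrp2 had log2 fold changes of -3.05, -2.49 and -2.39. Camera with a preset correlation called the secretory, progesterone and Wnt lists with adjusted p values of 5.0e-07, 2.84e-05 and 0.000252, which became adjusted p values of 0.430, 0.364 and 0.204 with an estimated correlation. The early estrogen list had a camera adjusted p of 0.069, which ran from 0.0269 to 0.0903 when single libraries were left out, under 0.05 without diestrus replicate 2, diestrus replicate 4 or estrus replicate 2, and was 0.0206 with no filter. Camera at the preset correlation called 13 of 35 lists in all, and 17 of the 35 possible splits of the libraries gave at least as many. When single libraries were left out, 12 to 16 secretory and 6 to 10 early estrogen genes rose, 0 to 2 early estrogen genes, 6 to 12 progesterone and 7 to 14 Wnt genes fell, and 0 to 2 Wnt genes rose. The fewest secretory and early estrogen rises and progesterone and Wnt falls came without estrus replicate 2. The most genes that changed in any other split of the libraries were 4, 7, 7 and 8 for the secretory, early estrogen, progesterone and Wnt lists. These came from the split that joined diestrus replicate 1 with the estrus libraries, since the remaining splits changed at most 2 genes in all.

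Of 20 tested luminal and glandular epithelium markers, 11 rose and none fell, as when adjusted over the list alone. Krt7 rose from 114.8 ± 30.4 to 653.6 ± 110 FPKM and the transcription factor Elf3 from 66.2 ± 23.3 to 554.3 ± 30.6. Of 18 tested stroma markers, none rose and 9 fell, or 10 adjusted over the list alone, with Thy1 falling from 95.4 ± 12.8 to 34.5 ± 4.32 FPKM. All 17 tested endothelium markers had negative log2 fold changes and 11 fell, or 14 adjusted over the list alone, with a median of -1.03. Without estrus replicate 2, 10 epithelium markers rose and 6 stroma markers fell, but no endothelium marker passed (adjusted p = 0.0537, 0.0506, 0.0615 and 0.0642 for Esam, Cldn5, Tek and Emcn), only 4 fell without estrus replicate 1, and 14 fell without diestrus replicate 1. The split that joined diestrus replicate 1 with the estrus libraries changed 7 epithelium, 5 stroma and 12 endothelium markers, the most of any other split. Of 21 smooth muscle markers, 1 rose and 1 fell, and none adjusted over the list alone. With single libraries left out, 0 to 1 rose and 0 to 4 fell. Camera called this list only with library weights (0.0434), without diestrus replicate 1 (adjusted p = 0.0406) or without estrus replicate 3 (0.0194), with values up to 0.785 when other libraries were left out. Camera called the epithelium, stroma and endothelium lists (adjusted p = 0.000603, 0.000268 and 1.62e-05), and with an estimated correlation their adjusted p values were 0.500, 0.450 and 0.525. The gland markers were divided: of 10 tested, 2 rose (Lif and Ltf), 3 fell (Foxa2, Fgfr2 and Wfdc3), or 2 and 5 adjusted over the list alone, and 1 to 2 rose and 2 to 5 fell when single libraries were left out. Lif, the cytokine required for implantation, rose by 2.08, and Ltf, lactotransferrin, had a log2 fold change of 3.25 with an adjusted p of 0.0257 that became 0.0581 without diestrus replicate 3 and 0.0559, 0.0875 and 0.0694 without estrus replicates 1 to 3. The gland proteases Prss28 and Prss29 and the trypsin inhibitor Spink3, named after their values were seen, did not pass (adjusted p = 0.0651, 0.0959 and 0.0750), and Prss28 ranged from 6.62 to 3411 FPKM among the diestrus libraries.

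**Figure D2:**
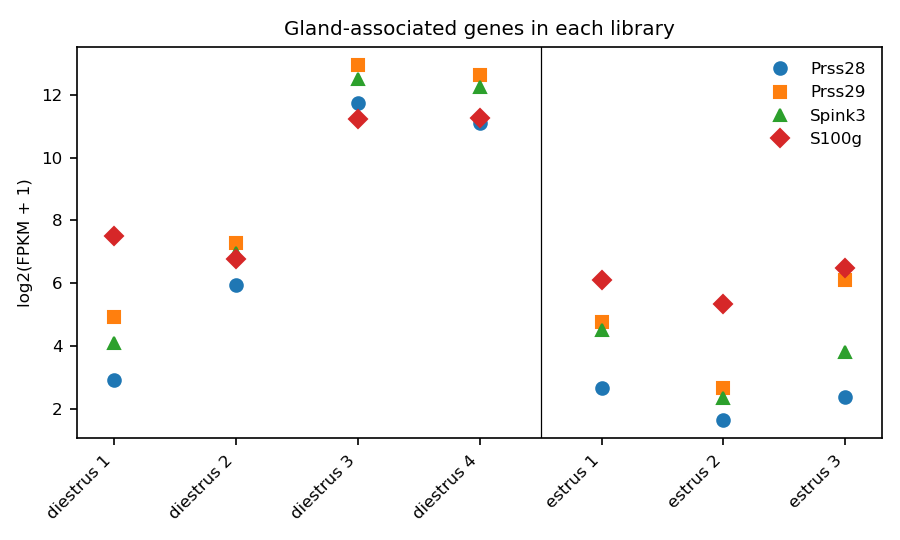
FPKM of Prss28, Prss29, Spink3 and S100g, as log2(FPKM + 1), in each of the 4 diestrus and 3 estrus libraries. Prss29 was at 7952 and 6335 FPKM in diestrus replicates 3 and 4, at 29.5 and 155.5 in replicates 1 and 2, and at no more than 67.4 in estrus.

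Of 18 macrophage and dendritic cell markers 7 fell, of 11 class II antigen presentation genes 6 fell, of 10 eosinophil and mast cell markers 4 fell, of 13 lymphocyte markers 4 fell and 1 rose, and of 6 neutrophil markers 1 fell. Adjusted over the list alone, the numbers that fell were 9, 8, 5, 7 and 2 in the same order. Without estrus replicate 2 they were 0, 1, 1, 1 and 1: Ms4a7, Csf1r, Lyz2 and Clec9a were then at adjusted p values of 0.0577, 0.0718, 0.0865 and 0.157, Cd74, H2-Ab1 and H2-DMa at 0.0667, 0.0747 and 0.0797, and the mast cell proteases Cma1, Mcpt4 and Tpsb2 at 0.0838, 0.084 and 0.0991. The most that fell with another library left out were 11, 8, 5, 7 and 2, and another split of the libraries changed up to 11, 6, 0, 6 and 1 genes of these lists. The 11, 6 and 6 came from the split that joined diestrus replicate 1 with the estrus libraries. Cd83, a marker of mature dendritic cells, the mast cell protease Cpa3 and the histamine-forming enzyme Hdc had log2 fold changes of -2.48, -1.58 and -2.88 and passed in every setting. Hdc was the neutrophil marker that fell. Its diestrus mean was 110.4 FPKM, against 1.38, 1.03 and 6.27 for Csf3r, S100a9 and Mmp9 of that list, which did not pass. Cd79b was the lymphocyte marker that rose, from 1.90 ± 0.79 to 7.22 ± 0.90 FPKM. Camera called the first 4 of these lists (adjusted p = 0.0014, 0.00141, 0.0102 and 0.00912), whose adjusted p values with an estimated correlation were 0.590, 0.525, 0.500 and 0.525. Of 24 interferon response genes, 15 rose and none fell, or 16 adjusted over the list alone and 10 to 16 when single libraries were left out, including the antiviral GTPase Mx1, which rose by 2.75 and shares sequence with Mx2. Camera called the interferon list (adjusted p = 4.33e-05), with an adjusted p of 0.525 with an estimated correlation. Of 24 chemokine and cytokine genes, 10 rose and 3 fell, or 11 and 4 adjusted over the list alone. The eosinophil attractant Ccl11 rose from 15.01 ± 3.71 to 131.0 ± 39.3 FPKM and Cxcl5 rose by 3.25, while Cxcl14 fell by 1.51. Camera did not call this list (adjusted p = 0.0561), but did so with adjusted p values of 0.0121, 0.0349 and 0.0156 without diestrus replicates 2, 3 and 4, 0.0385 with median-ratio scaling, 0.0114 with quantile normalization and 0.0159 with the replicate block. It was not called without diestrus replicate 1 (0.203) or estrus replicates 1 to 3 (0.152, 0.152 and 0.407), and 6 to 11 of its genes rose and 1 to 5 fell when single libraries were left out, with 6 and 1 without estrus replicate 2.

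**Figure D3:**
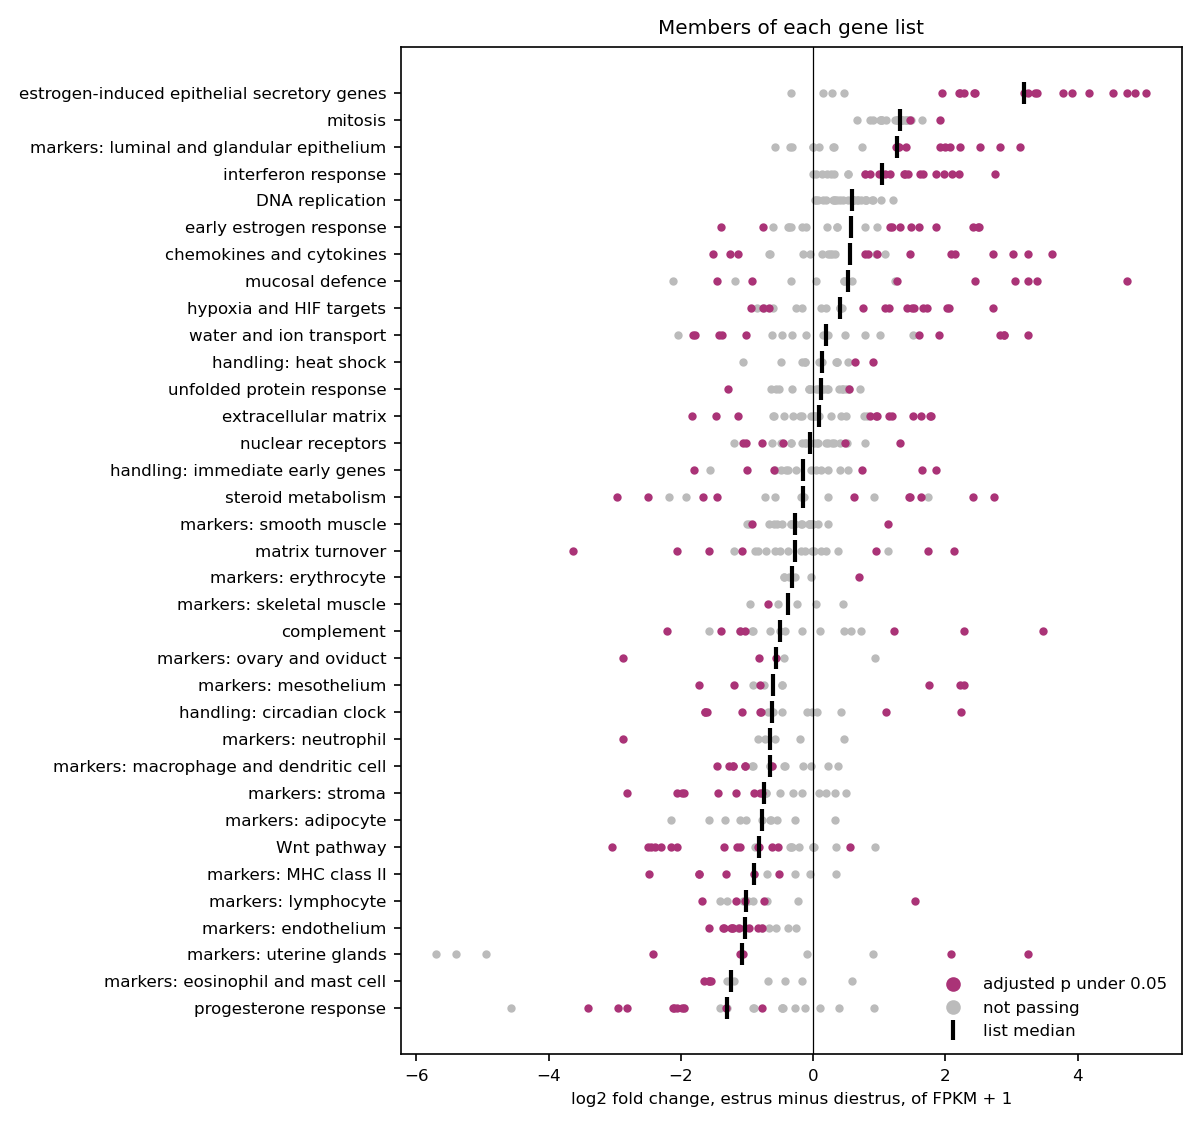
Log2 fold change, estrus minus diestrus, of each tested member of the 35 lists with at least 5 tested members, ordered by the list median (black bar). Coloured points passed an adjusted p of 0.05 in limma, and the medians run from -1.31 for progesterone response to 3.20 for estrogen-induced epithelial secretory genes.

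Of 25 hypoxia and HIF target genes, 11 rose and 3 fell, or 11 and 4 adjusted over the list alone. The rises were 7 to 12 and the falls 0 to 2 when single libraries were left out, with 7 and 0 without estrus replicate 2. Egln3, a HIF prolyl hydroxylase, rose from 4.69 ± 0.48 to 37.7 ± 12.8 FPKM and the carbonic anhydrase Car9 rose by 2.05. Camera called this list (adjusted p = 0.0375), with an adjusted p of 0.566 with an estimated correlation, and at the preset correlation of 0.158 among genes with a mean of at least 5 FPKM, 0.0515 without diestrus replicate 2 and 0.0903 without estrus replicate 3. All 25 tested mitosis genes had positive log2 fold changes with a median of 1.31, but only Cenpe and Mad2l1 passed (adjusted p = 0.0206 and 0.038), and none adjusted over the list alone. Without estrus replicate 2 these p values were 0.0896 and 0.136, without estrus replicate 1 they were 0.0711 and 0.120, without diestrus replicate 4 they were 0.0524 and 0.0847, and Mad2l1 was at 0.0833 without diestrus replicate 3. Without estrus replicate 3, by contrast, 23 mitosis genes passed, all higher. Camera called the mitosis list (adjusted p = 0.000695), with an adjusted p of 0.750 with an estimated correlation. None of 27 DNA replication genes passed, and camera did not call their list (adjusted p = 0.132). Without estrus replicate 3 that list was called (adjusted p = 0.00036), 2 of its genes passed, with Rrm1 at 0.0392, and so did the mitosis genes Ccnb1 and Kif23 (0.0116 and 0.0291). Without diestrus replicate 2 the list (0.0178) and Kif23 (0.0365) passed. The list was also called with library weights (0.0136), and without other libraries its adjusted p reached 0.989. In water and ion transport, 6 of 22 rose and 5 fell, with Car2 rising from 118.4 ± 18.5 to 843.0 ± 125 FPKM and the chloride channel Ano1 falling from 33.3 ± 1.97 to 11.8 ± 0.74. In steroid metabolism, 6 of 20 rose and 4 fell, with the oxytocin receptor Oxtr rising by 2.42 and the prostaglandin F receptor Ptgfr falling from 4.00 ± 1.48 to 0.53 ± 0.19 FPKM. Over the fits without single libraries, 4 to 6 transport genes rose and 3 to 6 fell, and 3 to 6 steroid genes rose and 2 to 7 fell, with 4 and 3 and with 3 and 2 without estrus replicate 2.

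In the extracellular matrix list, 9 of 29 genes rose and 3 fell, with Fbln2 and Col6a3 rising by 1.76 and 1.78 and Col12a1 falling from 10.7 ± 1.26 to 4.26 ± 0.37 FPKM. In matrix turnover, 3 of 22 rose and 4 fell, with the gelatinase Mmp2 falling from 272.8 ± 47.7 to 90.5 ± 18.0 FPKM. In mucosal defence, 6 of 16 rose and 2 fell, with the mucins Muc1, Muc4 and Muc20 rising by 2.45, 3.39 and 3.05. In complement, 3 of 19 rose and 4 fell, with Cfb rising by 3.48 and Masp1 falling from 6.90 ± 2.15 to 0.65 ± 0.21 FPKM. In the unfolded protein response, 1 of 22 rose and 1 fell. Adjusted over the list alone, the rises and falls were 9 and 3 for extracellular matrix, 3 and 4 for matrix turnover, 6 and 3 for mucosal defence, 3 and 7 for complement, 0 and 1 for the unfolded protein response, 6 and 5 for water and ion transport and 6 and 5 for steroid metabolism. When single libraries were left out, 3 to 10 extracellular matrix genes rose and 2 to 4 fell, 3 matrix turnover genes rose and 2 to 4 fell, 4 to 7 mucosal defence genes rose and 0 to 3 fell, 2 to 3 complement genes rose and 2 to 7 fell, and 0 to 1 unfolded protein response genes rose and 1 fell. Without estrus replicate 2 the rises and falls were 3 and 2, 3 and 2, 4 and 0, 2 and 2, and 0 and 1 in the same order. The split that joined diestrus replicate 1 with the estrus libraries changed 8 complement genes. None of these lists was called by camera, whose adjusted p values ran from 0.137 for mucosal defence to 0.920 for steroid metabolism and for water and ion transport. Mucosal defence was called without diestrus replicate 2 (0.0332) or 4 (0.0335), and complement without diestrus replicate 1 (0.0416), with values up to 0.297 and 0.515 without other libraries.

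Lists that mark other tissues or tissue handling gave these counts. Of 17 circadian clock genes, 2 rose and 6 fell, or 2 and 8 adjusted over the list alone, with Bhlhe40 rising by 2.24 and Nr1d1 falling from 38.4 ± 11.2 to 12.03 ± 4.77 FPKM. The time of day of collection is not given in the sources used here. Of 18 immediate early genes, 3 rose and 3 fell. Of 13 heat shock genes 2 rose. Of 5 ovary and oviduct markers 3 fell, of 6 skeletal muscle markers 1 fell, of 6 erythrocyte markers 1 rose, and none of 11 adipocyte markers passed. Of 10 mesothelium markers, 3 rose and 3 fell, with a mean of -0.0063 against a median of -0.60, and Krt19, also an epithelial keratin, rose by 2.23. None of 3 tested stratified squamous epithelium markers passed, and their number was below the minimum for a list test. Adjusted over the list alone, the rises and falls were 3 and 3 for immediate early genes, 2 and 0 for heat shock, 3 and 4 for mesothelium, 0 and 3 for ovary and oviduct, 0 and 1 for skeletal muscle and 0 and 0 for erythrocytes. In fits that left out single libraries, 1 to 3 circadian genes rose and 2 to 8 fell, 0 to 3 immediate early genes rose and 0 to 5 fell, 1 to 2 heat shock genes rose and 0 to 1 fell, 2 to 3 mesothelium markers rose and 1 to 3 fell, 1 to 3 ovary and oviduct markers fell, 0 to 1 skeletal muscle markers rose and 0 to 2 fell, 0 to 1 erythrocyte markers rose, and 0 to 1 adipocyte and 0 to 1 squamous markers fell. Without estrus replicate 2, 2 circadian genes rose and 2 fell, and no immediate early gene passed. Camera called none of these lists, and the lowest adjusted p among them was 0.0541, for the circadian clock list. That list was called without diestrus replicate 3 (0.0349) or estrus replicate 3 (0.0225), the adipocyte list without diestrus replicate 2 (0.0332) or estrus replicates 2 (0.0292) or 3 (0.0381), and the ovary and oviduct list without diestrus replicate 4 (0.0406). Without other libraries these 3 lists reached 0.0838, 0.638 and 0.128. The circadian list was also called at a mean of at least 5 FPKM (0.029) and with library weights (0.039), and the adipocyte list with the replicate block (0.0286).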

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

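The tests of the spread between diestrus libraries and of diestrus replicate 1 were chosen after the results were seen, except the test of admixed estrus RNA. Among 163 measures examined over the 4 diestrus libraries, 13 had a highest or lowest library separated from the others by more than Dixon's 95% critical value, and chance gives about 1 in 20. Of these, 7 were set by diestrus replicate 1. In it, AK178082 was at 130885 FPKM and AK188772 at 81.7, each listed at 0 in the other diestrus libraries, Hspe1 was at 28.8 against at most 20.7, Thy1 at 76.3 against at least 100.4, H2-DMa at 5.17 against at least 8.77, Cd3g at 1.66 against at least 2.54, and the FPKM sum was 583079 against at most 482443. That sum includes the 130885 FPKM of AK178082, so the sum and that row are not separate signs. In estrus replicates 1 to 3, AK178082 was at 137308, 143298 and 197099 FPKM and AK188772 at 105.6, 133.2 and 137.4. At these 2 rows diestrus replicate 1 therefore lay nearer to estrus than to the other diestrus libraries. Diestrus replicate 2 stood apart in Egln3 (5.40 against at most 4.50 FPKM) and in Hba-a2 (137.8 against at least 526.9). Diestrus replicate 3 stood apart in Lef1 (17.9 against at most 6.80), Oas2 (9.05 against at most 3.69), Krt10 (3.22 against at most 2.06) and Lor (0.438 against at least 1.07).

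Diestrus replicate 1 lay nearest to the estrus libraries, and the split that joined it with them gave 2661 changed genes. An estrus library under a diestrus label would lie nearer to the estrus mean at most of the 5311 genes called without it, and it did so at 39.8%. The rows AK178082 and AK188772 were among those at which it lay nearer to estrus. Admixed estrus RNA would give about 1 share of estrus RNA at all genes, but over the 258 genes at least 4-fold higher in estrus without this library the first quartile of the implied share was -1.03% and the third 14.97%, and at the 156 genes at least 4-fold lower its median level was 39.2% of the other diestrus mean, far below what such a share allows. Because the first quartile was below 0, the ratio of quartiles named in advance had no meaning and the quartiles are given instead. The labels name no stage within diestrus, so no biological explanation was tested.

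Prss28, Prss29 and Spink3 lay far apart between diestrus libraries. In diestrus replicates 1 to 4, Prss28 was at 6.62, 61.1, 3411 and 2180 FPKM, and Spink3 at 16.2, 122.8, 5835 and 4900. Pancreas carried over would bring its other abundant transcripts, but the highest gene of a pancreas list reached 0.734% of Spink3. A larger gland share as the whole cause is argued against only for the other 7 gland markers that passed the expression filter. Their highest-to-lowest ratio over diestrus libraries was at most 15.9 against at least 261 for the 3 genes. Cxcl15, a gland marker that the filter left out, also ranged widely, at 35.1, 8.15, 0.351 and 0.556 FPKM. It was highest in replicate 1, where the 3 genes were lowest. The ratio test was not run with it, and its range was wide enough to leave that test undecided. The test therefore does not settle the question for all gland markers. A larger gland share as part of the difference stays open: Wfdc3 was at 8.27, 1.82, 21.4 and 20.5 FPKM in diestrus replicates 1 to 4, while Aldh1a1 was at 91.4, 68.5, 10.6 and 13.7. No biological explanation was tested because the labels give 1 diestrus group.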

How the results depend on the processing

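All alternatives but the one without accession and small RNA rows were planned. The number of changed genes was 9367 (4944 higher, 4423 lower, 2604 at least 2-fold) with library weights, an estimate that stopped before it converged and gave estrus replicate 2 a weight of 62.9 against at most 0.95 elsewhere, so it rests on 1 library. It was 2281 (1299 higher, 982 lower) with a replicate block, in which diestrus replicate 4 has no partner and does not inform the difference. The fit without a block gave 2559 changed genes when diestrus replicate 4 was left out. Whether the numbers pair the libraries stays open: deviations of same-numbered libraries correlated at 0.198, 0.024 and 0.169, and 2 of 3 diestrus libraries correlated best with their own number. With a pseudocount of 5, 853 genes changed at least 2-fold, and with a mean of at least 5 FPKM 1181 genes were lower. Leaving out 1 library gave 1433 to 5311 changed genes, 854 to 2866 higher, 579 to 2445 lower, 958 to 2056 at least 2-fold and 13 to 17 lists. The list count was 0 with an estimated correlation (lowest adjusted p 0.204, 3 lists at an unadjusted p under 0.05) and 16 with fry. The interferon list was lost with library weights (adjusted p = 0.123) and the lymphocyte list at a mean of at least 5 FPKM (0.0698). Over the settings with camera at the preset correlation, 3 of 13 called lists were lost in at least 1 and 9 of 22 others were called in at least 1. With an estimated correlation all 13 were lost. All other alternatives kept each count within 1.5 times, and no scaling moved the median log2 fold change of all genes by over 0.1. Lor turned from -0.024 to 0.148 with quantile normalization, 0.0141 with the replicate block and -0.175 to 0.0590 without single libraries, and Krt10 from 0.015 to -0.0160 with median-ratio scaling, -0.105 with library weights, -0.0303 with the replicate block and -0.0322 to 0.138 without single libraries. Neither passed the test. Of 126 called genes among the 158 that the rule names, 84 passed in every limma setting and 42 were lost in at least 1, most often (41) without estrus replicate 2. The cause was not tested. In an exact permutation of each named gene, 33 of the called genes had an unadjusted p above 0.05. They included Slc5a11 and Slc6a2 (0.0571 each), which had passed in every limma setting.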

Other observations

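Gene families were chosen after the data were seen. Of 22 tested genes of a cholesterol synthesis list, 19 rose at estrus and none fell in limma, with a median log2 fold change of 1.57. The isomerase Idi1 rose from 1.97 ± 0.93 to 18.2 ± 6.63 FPKM and the squalene epoxidase Sqle from 7.85 ± 3.39 to 43.8 ± 16.0. Of 20 tested Hox genes, 12 fell and 1, Hoxb4, rose, with Hoxd10 falling from 44.7 ± 7.65 to 13.05 ± 2.09 FPKM. Of 43 rows with proteasome subunit names 18 rose and none fell, and of 17 mitochondrial ATP synthase rows 10 rose and none fell. Of 325 Zfp genes 85 fell and 11 rose, of 46 glycosyltransferase genes 17 rose and 5 fell, and all 3 tested metallothioneins fell, with Mt2 falling from 151.3 ± 47.4 to 45.7 ± 21.7 FPKM. Of 8 abundant stromal matrix genes 2 rose and none fell, with a median of 0.43, and the pancreas list had 1 tested gene, which fell. Apart from the pancreas list, unadjusted camera p values at the preset correlation ran from 7.63e-12 for cholesterol synthesis to 0.239 for stromal matrix. With an estimated correlation they ran from 0.0528 for Zfp genes to 0.560 for stromal matrix. These families were not refitted without single libraries.

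S100g, the vitamin D dependent calcium-binding protein calbindin D9k, chosen after its values were seen, was at 179.3, 107.1, 2428 and 2434 FPKM in diestrus replicates 1 to 4 and at 67.0, 39.5 and 87.8 FPKM in estrus replicates 1 to 3. Its limma adjusted p was 0.0696. Prss29, a serine protease, was at 29.5, 155.5, 7952 and 6335 FPKM in diestrus and at 25.9, 5.34 and 67.4 FPKM in estrus. Cxcl15, also chosen after its values were seen, was at 35.1, 8.15, 0.351 and 0.556 FPKM in diestrus and at 0.349, 0.139 and 0.0366 FPKM in estrus.

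The tests of splits were written before their results were seen, and the others below after. The real grouping gave 4336 changed genes, and 1 of the 35 splits, the real one, gave as many, with 2661 in the highest other split, which joined diestrus replicate 1 with the estrus libraries, and 2 in the next. The same held for genes higher (1 of 35, 2393 against 1288), lower (1 of 35, 1943 against 1373) and changed at least 2-fold (1 of 35, 1662 against 1048). These counts come from the same fits, and 35 splits allow no exact permutation p below 0.0286. They argue against chance only to that level. Chance cannot be excluded for the 13 gene lists called by camera: 17 of the 35 splits gave at least 13, the highest other gave 18, and the median of the others was 12. The camera p-values at the preset correlation therefore do not separate the cycle stages from other groupings of these libraries. In an exact permutation of each list's mean over libraries, added after this was seen, 14 of 35 lists reached the smallest p that the splits allow, 0.0286, against 1 expected by chance, 7 higher and 7 lower in estrus. The lists share libraries, and some share members, such as Hoxa10, Hoxa11 and Gli1 in the progesterone and stroma lists. They are not separate tests, so the excess over 1 does not measure the strength of evidence. No adjusted p was under 0.0715. The lists at that p included the secretory, interferon and epithelium lists among those higher and the progesterone, Wnt and stroma lists among those lower. They also included the circadian clock list, kept as a check of tissue handling, and the neutrophil list, of which 1 of 6 members (Hdc) passed, but not endothelium (0.0571), mitosis (0.143) or macrophages (0.0857).

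Of the tested markers, 9 of 18 for stroma, 11 of 17 for endothelium and 7 of 18 for macrophages and dendritic cells fell at estrus, and 11 of 20 for epithelium rose. Without estrus replicate 2 these counts were 6, 0, 0 and 10, and the highest in another split of the libraries were 5, 12, 11 and 7, so chance cannot be excluded for the endothelium and macrophage counts. A larger epithelial share that dilutes all other cells alike would move the endothelium and smooth muscle means together. Their difference moved by -0.705 on the log2 scale (exact permutation p = 0.0286, the smallest possible). This pair was chosen after the list results were seen, and changed expression per cell in either tissue would move it too. The test therefore cannot decide whether dilution was equal. A general lowering by the scaling of FPKM as the cause is argued against by the median of all tested genes, 0.048. After median-ratio scaling that median was 0.0082 and the endothelium median -1.08. With so small a shift the endothelium median could hardly move, so it is not a separate test. A smaller share of endothelial cells and lower expression per cell cannot be told apart in whole tissue, since all 17 negative endothelial markers are what either predicts. The difference in cycle stage itself stays open as an explanation.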
